A study of Mus musculus with 8 samples.

How the data were processed

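Expression was measured with single-colour Illumina bead arrays on total RNA from primary bone marrow-derived macrophages of mice. Per the labels, RNA was extracted with Trizol, cleaned on a column with DNase I treatment, and turned into biotinylated cRNA. The labels gave 4 groups, wild type unstimulated, wild type LPS, Bcl6 knockout unstimulated and Bcl6 knockout LPS, with technical replicates 1 and 2 in each. The dose and duration of LPS are not given in the sources used here. The authors deposited a mean bead intensity for each probe and array that was not normalized between arrays, as its medians of 112.1 to 130.2 show. The deposited detection p-value of each probe, set against the negative controls of its array, comes in steps of 1 in 936. A table of the authors' processed values holds an intensity for each probe on a linear scale. Its 8 columns have medians of 121.0, share nearly all quantiles and rank the probes as the raw columns do (rho of 1), so they were normalized between arrays by quantiles or a close relative. Neither table appears background-subtracted, and the normalization method is not given in the sources used here. GenomeStudio is the tool named in the submitters' processing notes, without a version. Columns of samples outside the series numbered 0.

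From the raw intensity, background was corrected with limma's nec function, which fits a normal-exponential model to negative controls inferred from the detection p-values, with an offset of 16. Arrays were then quantile-normalized on the log2 scale. Probes with a detection p under 0.01 on at least 2 arrays were kept, 14418 of 45281. Probe names came from a platform annotation that listed 34903 probes, 34885 with 1 gene symbol and 18 with several, and 10378 probes unnamed here. Symbols were updated through gene identifiers or accessions to the RefSeq annotation of GRCm38.p6, which matched 34818 probes. That annotation was used only for names and for which genes neighbour each other. Of the kept probes 12542 had 1 gene, and each gene was represented by its brightest probe, leaving 8306 genes. Depth does not apply to arrays, and the number of arrays limits the precision.

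One limma model with a mean for each of the 4 groups was fitted over all 8 arrays, with 4 residual and 4.57 prior degrees of freedom. Moderated tests were adjusted by Benjamini-Hochberg within each of 7 contrasts. These were the LPS effect in each genotype, the knockout effect in each treatment, the difference of the LPS effect between genotypes, and the mean LPS and mean knockout effects. Genes with an adjusted p under 0.05 and at least a 2-fold change were called. Where both arrays of a group failed detection, a change between groups is given only as at least N-fold. That bound sets the brighter group's mean against the mean over the dimmer group's arrays of the higher of the lowest detected signal and the probe's own signal. No fold is given where both groups failed. The difference of the LPS effect is given as fitted, without such a bound. The arrays of a group are technical replicates of what may be 1 culture, so p-values do not cover variation between mice.

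Before the data were examined, the groups, tests, alternatives, 28 gene lists and the rule for named genes were fixed. The rule took Bcl6 first. For each comparison between groups it took up to 12 genes higher and 12 lower with the largest change among called genes with a symbol. These had to be detected on both arrays of the brighter group, with both arrays of one group beyond both of the other. For the difference of the LPS effect it took up to 8 in each direction, and for each described list the 2 to 4 members with the largest change. Symbols of clones were passed over, and Rik, Gm, LOC and accession-like names were read as such. Lists with at least 3 tested members, 21 in number, were tested with camera at a preset correlation of 0.01, adjusted over the 147 tests of 21 lists and 7 contrasts. The same test with an estimated correlation, and fry, were alternatives. A further 6 marker lists had too few tested members, and 1 list checked the sex given in the labels. Medians were set against 10000 random lists matched on mean expression. With members below background at their bound, and at 0 where both groups failed detection, no list median took the opposite sign. Some medians fell to 0, among them that of inflammatory cytokines for the knockout effect unstimulated and that of matrix proteases for LPS in wild type. The list tests used the signals as fitted, without the bounds.

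The model fit and the calling rule were tested on simulated data for the LPS effect in wild type, with 200 of 8306 genes changed. They called 93 of 100 genes changed by 1.5 log2 units and 100 of 100 changed by 3, with 0 false calls. The simulated noise was independent and had only the spread between technical replicate arrays. Background correction, normalization, the filter and the choice of probe were not tested by it. Variation between mice or cultures was not simulated. Alternatives covered background correction, scaling, the filter, the fold minimum, the choice of probe, the arrays in the fit, the replicate number as a block, averaged arrays, eBayes settings and leaving out each array. The slide as a block was not run, because the column names give no slide. R 4.3.3, limma 3.58.1 and version 1.17.8 of data.table were used.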

Results

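Gene expression was measured in primary mouse macrophages grown from bone marrow, from wild-type mice and from mice labelled as Bcl6 knockouts. Bcl6 is a zinc-finger protein that represses transcription. Cells of each genotype were either left unstimulated or stimulated with LPS, the bacterial cell-wall lipid that macrophages sense through the receptor Tlr4. Each of the 4 combinations was hybridised to 2 bead arrays, giving 8 arrays. The labels call the arrays of a group technical replicates, so n = 2 arrays of each group throughout, and the p-values measure only the spread between such arrays. No spread between mice or cultures enters any test.

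Each array held 45281 probes, of which 11857 to 13209 were detected above the array's negative controls. The fewest were on replicate 1 of the Bcl6 knockout LPS group. Median raw signal was lowest on the Bcl6 knockout LPS arrays, at 113.7 and 112.1, and highest on the wild-type unstimulated arrays, at 130.2 and 128.2. After normalization, the arrays of a group correlated across the 8306 tested genes with r from 0.993 to 0.995. Arrays of different groups correlated with r from 0.882 to 0.953. These correlations are across genes, which are not independent replicates. The number of arrays limits the precision of every value. Changes are given as log2 fold ± the standard error of the limma fit. A gene was called at an adjusted p under 0.05 and a change of at least 2-fold.

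The Bcl6 transcript was read by 1 probe. Its log2 signal was 10.95 and 10.92 on the wild-type unstimulated arrays and 10.75 and 10.99 on the wild-type LPS arrays. On the arrays labelled Bcl6 knockout it was 12.60 and 12.33 without LPS and 9.92 and 9.93 with LPS. Relative to wild type, the signal was thus higher in the unstimulated labelled knockout, by 1.53 ± 0.13, with limma's adjusted p = 4.76e-05. Under LPS the change was -0.94 ± 0.13, with limma's adjusted p = 0.000616, which did not reach 2-fold, and with median scaling between arrays it was -1.26, or -0.97 relative to a median over all genes of -0.29. The labels do not say which part of the gene was deleted, and the position of the probe in the transcript was not used here. The probe therefore does not settle the genotype. The signal in the unstimulated cells shows no loss of the probed transcript. A probe outside the deleted part and a mislabelled group cannot be told apart here. Every direction below refers to the arrays labelled knockout. As a check of the label that the mice were male, the Y-linked gene Eif2s3y was detected on 8 of 8 arrays by 1 of its 2 probes, and the 4 probes of the female-specific transcript Xist were detected on 0 arrays.

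**Figure D1:**
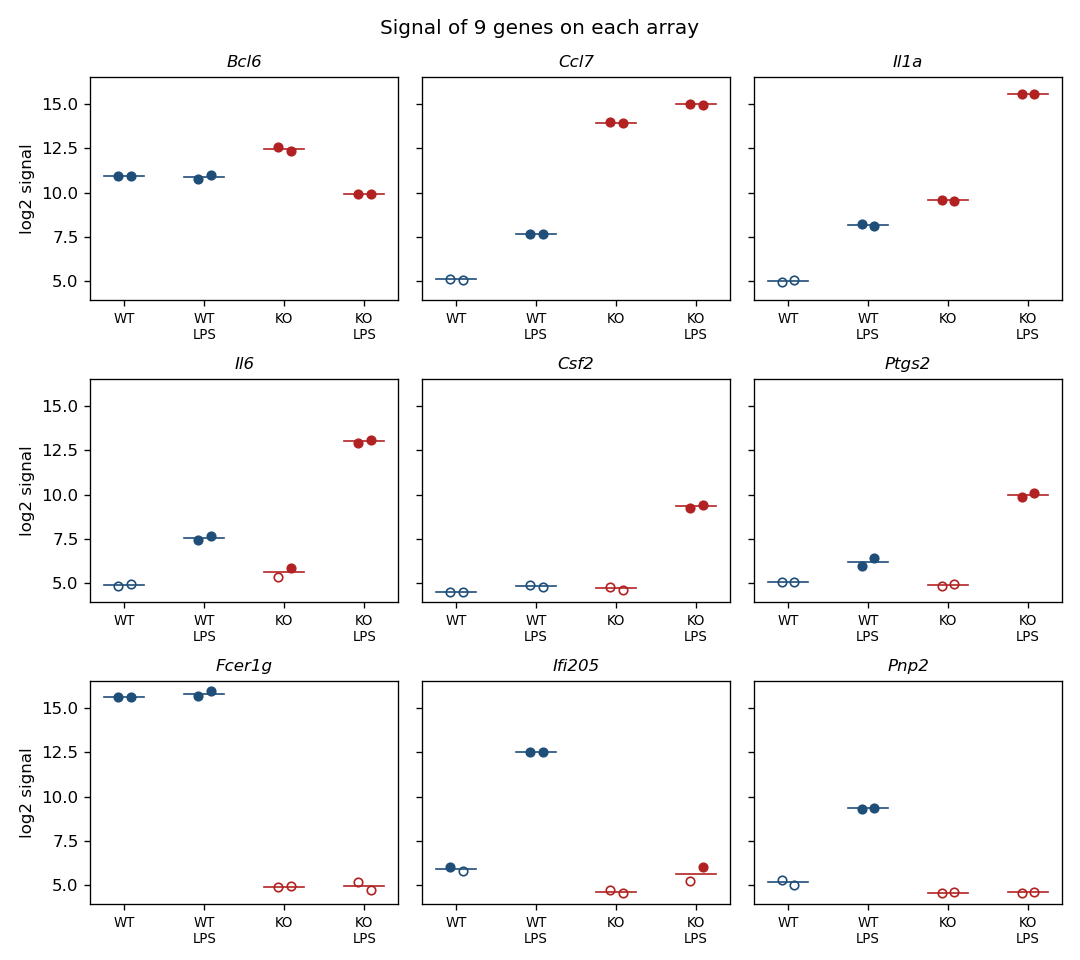
Log2 signal of 9 genes on each of the 8 arrays, by group (WT, wild type; KO, labelled Bcl6 knockout). Each point is 1 array, filled where the probe was detected and open where it was not, and each line is the mean of the 2 arrays of a group; Bcl6 lies highest on the unstimulated labelled knockout arrays, at 12.60 and 12.33.

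The first comparison asked how wild-type macrophages responded to LPS. The neutrophil attractants Cxcl1 and Cxcl2 changed by 6.41 ± 0.10 and 5.33 ± 0.13, the pyrogenic cytokine Il1b by 5.26 ± 0.13 and the costimulatory receptor Cd40 by 5.70 ± 0.14. The largest fitted rise was that of Ifi205, an interferon-inducible gene, at 6.62 ± 0.23, although its probe was detected on only 1 of the 2 unstimulated arrays. Socs3, a feedback inhibitor of cytokine signalling, rose by 4.77 ± 0.11, the activation marker Cd69 by 4.44 ± 0.14 and the chemokine Cxcl10 by 4.35 ± 0.16. The guanylate-binding protein Gbp5, the vasoconstrictor peptide Edn1, the transcriptional regulator Tsc22d1 and the antiviral GTPase Mx1 were not detected without LPS. They were at least 14.8-fold, 11.1-fold, 14.2-fold and 10.7-fold higher with it.

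Genes lower with LPS in wild-type cells included St6gal1, a sialyltransferase, at -3.68 ± 0.13 and the cell-cycle gene Ccnd1, which encodes cyclin D1, at -3.46 ± 0.13. The palmitoyltransferase gene Zdhhc14 changed by -3.29 ± 0.10, the lysophosphatidic acid receptor Lpar6 by -3.09 ± 0.15 and the RNA-decay factor Zfp36l1 by -3.04 ± 0.13. The dynein gene Dnah11 changed by -2.96 ± 0.23 and the nucleotide receptor P2ry6 by -2.83 ± 0.14. The chemokine receptor Cxcr4, the cannabinoid receptor Cnr2 and the oxysterol receptor Gpr183 fell below detection and were at least 14.0-fold, 8.26-fold and 5.45-fold lower. Gprc5b and the pseudogene Hmga2-ps1 also fell below detection, at least 5.13-fold and 4.24-fold lower. The adjusted p of these 24 genes was at most 1.41e-05.

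By gene list, 39 of 43 tested interferon-stimulated genes rose in wild-type cells and 0 fell (camera adjusted p = 4.08e-28, and adjusted p = 0.0134 with an estimated correlation). Among inflammatory cytokines 12 of 21 rose (camera adjusted p = 1.24e-10, and adjusted p = 0.0427 with an estimated correlation). Tnf, a central inflammatory cytokine, changed by 4.14 ± 0.13. Of the chemokines 11 of 17 rose (camera adjusted p = 2.76e-07, and adjusted p = 0.0654 with an estimated correlation), among them Ccl5 at 4.02 ± 0.12. The NF-kappaB family and its feedback regulators had 20 of 31 members higher (camera adjusted p = 5.24e-14, and adjusted p = 0.0242 with an estimated correlation), including Nfkbiz at 3.85 ± 0.14. Effector enzymes had 11 of 21 higher and 1 lower (camera adjusted p = 7.06e-05, and adjusted p = 0.0654 with an estimated correlation). Prostaglandin E synthase, Ptges, changed by 3.92 ± 0.17, and the nitric oxide synthase Nos2 was at least 3.93-fold higher. In the MHC class I list 5 of 17 rose (camera adjusted p = 1.07e-06, and adjusted p = 0.059 with an estimated correlation), among them the peptide transporter Tap2 at 2.14 ± 0.14. In the MHC class II list 2 of 13 rose, Cd40 and H2-Ab1 (camera adjusted p = 0.0336, and adjusted p = 0.143 with an estimated correlation), a call lost without replicate 2 of wild type unstimulated. For Toll-like receptor signalling the count was 4 of 27 (camera adjusted p = 0.00431, and adjusted p = 0.0817 with an estimated correlation), with Tlr1 at 2.71 ± 0.16. Cell-cycle genes went the other way, with 7 of 39 lower and 0 higher (camera adjusted p = 2.7e-05, and adjusted p = 0.0654 with an estimated correlation).

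In all, 1165 of 8306 genes were called for LPS in wild-type cells, 625 higher and 540 lower. The median change of all genes was -0.12, and relative to that median 750 were higher and 419 lower. Without background correction, which shrinks folds of dim probes, the count was 635.

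The same question was asked of the arrays labelled knockout. There the largest fitted rise with LPS was that of the cytokine Il6, at 7.41 ± 0.18, with the probe detected on 1 of the 2 unstimulated arrays. Il1b changed by 6.29 ± 0.13, Il1a by 6.03 ± 0.11, Cxcl1 by 6.02 ± 0.10, Cd40 by 5.69 ± 0.14 and the protease inhibitor Serpinb2 by 5.95 ± 0.11. Edn1, the amino acid oxidase Il4i1 and Gbp5 were undetected without LPS and at least 58.4-fold, 38.7-fold and 27.6-fold higher with it. The receptor Slamf1, the Ras activator Rasgrp1 and the interleukin-12 subunit Il12a were at least 19.8-fold, 27.1-fold and 24.1-fold higher. Among genes that fell, Ccnd1 changed by -4.42 ± 0.13, the immediate-early gene Fos by -4.05 ± 0.12, the glycosyltransferase Gcnt1 by -3.82 ± 0.22, St6gal1 by -3.46 ± 0.13, Lpar6 by -3.21 ± 0.15, Tmem86a by -3.14 ± 0.12 and Zdhhc14 by -2.98 ± 0.10. Cnr2, Ccsap, Dnah11, Pdcd4 and Gpr183 fell below detection, by at least 10.0-fold, 8.75-fold, 6.91-fold, 4.001-fold and 3.86-fold. The adjusted p of these genes was at most 5.18e-06.

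In the labelled knockout, 31 of 43 interferon-stimulated genes (camera adjusted p = 2.12e-22, and adjusted p = 0.0134 with an estimated correlation) and 18 of 21 inflammatory cytokines (camera adjusted p = 1.61e-16, and adjusted p = 0.025 with an estimated correlation) rose with LPS. So did 23 of 31 NF-kappaB genes (camera adjusted p = 5.96e-18, and adjusted p = 0.0218 with an estimated correlation) and 10 of 17 chemokines (camera adjusted p = 7.83e-09, and adjusted p = 0.059 with an estimated correlation). Effector enzymes had 10 of 21 higher (camera adjusted p = 4.45e-05, and adjusted p = 0.0654 with an estimated correlation), with the prostaglandin-forming cyclooxygenase Ptgs2 at least 17.8-fold higher. The MHC class I list had 5 of 17 higher (camera adjusted p = 0.000195, and adjusted p = 0.0744 with an estimated correlation), and the MHC class II list 3 of 13 (camera adjusted p = 0.00613, and adjusted p = 0.0886 with an estimated correlation). Toll-like receptor signalling had 4 of 27 higher and 2 lower (camera adjusted p = 0.00138, and adjusted p = 0.0654 with an estimated correlation). Of the cell-cycle genes 15 of 39 fell (camera adjusted p = 4.75e-08, and adjusted p = 0.0532 with an estimated correlation), including the replication factor Mcm2 at -1.77 ± 0.12. Granulocyte markers had 3 of 16 higher and 0 lower (camera adjusted p = 0.0127, and adjusted p = 0.102 with an estimated correlation), among them Lcn2 at 2.87 ± 0.12. Matrix proteases and inhibitors had 7 of 19 higher and 1 lower (camera adjusted p = 0.00496, and adjusted p = 0.0842 with an estimated correlation). Of genes described as repressed by Bcl6 in B cells, 5 of 11 rose and 2 fell (camera adjusted p = 0.0435, and adjusted p = 0.241 with an estimated correlation), a call also lost with cyclic loess and without replicate 2 of wild type unstimulated, replicate 2 of wild type LPS or replicate 1 of labelled knockout LPS.

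The labelled knockout had 1233 genes called for LPS, 622 higher and 611 lower; relative to a median over all genes of -0.12 these were 750 and 466. With median scaling in place of quantile normalization the split was 497 higher and 939 lower, with a median over all genes of -0.28. Relative to that median it was 737 higher and 494 lower, and without background correction, as in the main fit, more genes were higher (391) than lower (250). The LPS effects of the genotypes, which share no array, correlated across genes with r = 0.83. Called genes higher in both numbered 427, where independent lists would share 46.8, and genes lower in both numbered 352, where independent lists would share 39.7. No gene was called in opposite directions.

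**Figure D2:**
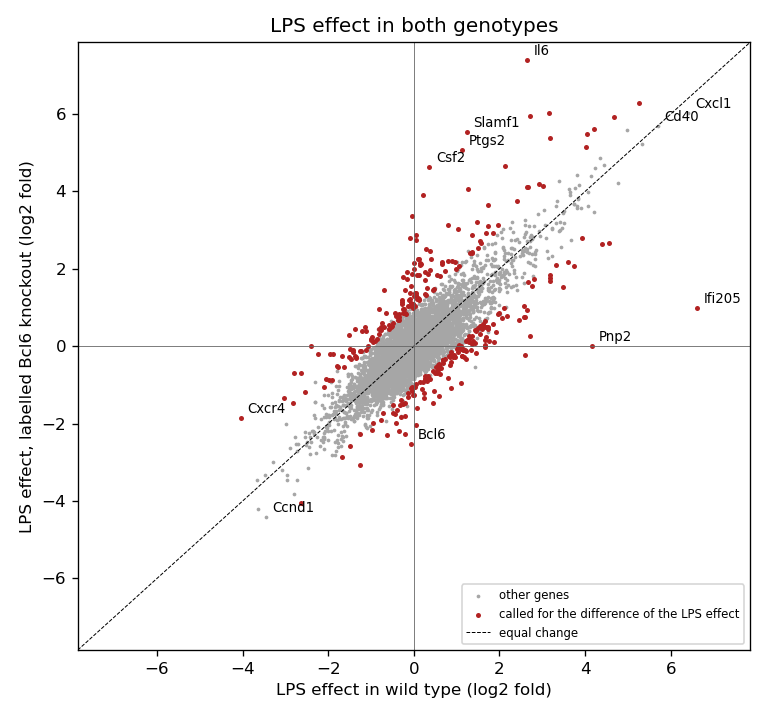
LPS effect of each of the 8306 genes in wild-type cells (horizontal axis, log2 fold) and in the labelled Bcl6 knockout (vertical axis, log2 fold), with the dashed line at equal change. Red points are the 318 genes called for the difference of the LPS effect; Il6, Slamf1, Csf2 and Ptgs2 lie above the line, and Ifi205 and Pnp2 below it.

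The arrays labelled knockout were next compared with wild type without stimulation. The chemokine Ccl7 was undetected in wild type and at least 270-fold higher in the labelled knockout. Ccl2 changed by 7.64 ± 0.16, with 1 of 2 wild-type arrays detecting it, and Ccl8 by 6.14 ± 0.16. Ccl12 was at least 18.3-fold higher. Of 17 tested chemokines 9 rose and 2 fell (camera adjusted p = 4.35e-05, and adjusted p = 0.0842 with an estimated correlation). Among inflammatory cytokines 8 of 21 rose and 1 fell (camera adjusted p = 0.000296, and adjusted p = 0.0744 with an estimated correlation). The list median was 0.22 as fitted and 0 with members below background at their bound. The cytokine Il1a and the macrophage growth factor Csf1 were at least 12.8-fold and 13.7-fold higher, Inhba, which encodes an activin subunit, changed by 4.53 ± 0.12 and Il1b by 3.43 ± 0.13. Other genes undetected in wild type were Hal, encoding histidine ammonia-lyase, the lysosomal protease gene Ctsl, Rhobtb1 and Tmem53, at least 48.9-fold, 36.2-fold, 14.6-fold and 11.2-fold higher. Tmem154 changed by 4.52 ± 0.12. A second probe of Rhobtb1 read a smaller change of 1.83.

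The largest decrease was that of Fcer1g, the signalling chain shared by several Fc receptors. On its only kept probe it fell from a mean log2 signal of 15.63 to below detection and was at least 902-fold lower. The receptor Fcgr3, which pairs with this chain, changed by 2.34 ± 0.11. Gpr137b-ps changed by -6.96 ± 0.18, the import receptor Tomm22 of mitochondria by -3.996 ± 0.11, the proteasome subunit Psmd8 by -3.88 ± 0.18, Fblim1 by -4.08 ± 0.15 and Tmem51 by -3.58 ± 0.17. The corepressor Tle1, the mitochondrial tRNA synthetase Lars2 and Fam83f were at least 13.5-fold, 8.10-fold and 4.79-fold lower. Another probe of Tle1 read a smaller change of -2.80. The chromatin factor Supt16 changed by -4.13 ± 0.16 on its brightest probe, but by 0.40 on a second probe. The complement gene C1qb changed by -3.55 ± 0.12 and the lipoprotein gene Apoe by -3.33 ± 0.21. The adjusted p of the 24 genes named by rule here was at most 9.44e-06. Of those that were lower, only Tle1 and Supt16 had a further kept probe. The other decreases rest on a single probe each.

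Cell-cycle genes were higher in the unstimulated labelled knockout, 13 of 39 with 0 lower (camera adjusted p = 3.72e-11, and adjusted p = 0.0427 with an estimated correlation). Thymidylate synthase, Tyms, changed by 1.92 ± 0.13 and the replication factor Cdc6 by 1.73 ± 0.12. Matrix proteases and their inhibitors had 7 of 19 higher (camera adjusted p = 0.0123, and adjusted p = 0.0984 with an estimated correlation). The urokinase gene Plau changed by 4.48 ± 0.11 and the collagenase gene Mmp13 by 3.55 ± 0.12. Macrophage identity genes had 5 of 20 lower and 1 higher (camera adjusted p = 0.0127, and adjusted p = 0.137 with an estimated correlation). Among them were Aif1 at -2.38 ± 0.11 and C1qc at -2.01 ± 0.16. Markers of granulocytes and their precursors had 12 of 16 lower and 0 higher (camera adjusted p = 3.98e-08, and adjusted p = 0.0427 with an estimated correlation). The granule genes Ngp and Mpo changed by -2.14 ± 0.12 and -2.65 ± 0.20, with Mpo detected on 1 of 2 labelled knockout arrays, and Elane was at least 4.06-fold lower. Alternative activation genes went both ways, 6 of 14 higher and 4 lower (camera adjusted p = 0.806), with F13a1 at 2.12 ± 0.16 and Chil4 at -2.26 ± 0.12. Of genes described as repressed by Bcl6 in B cells, 3 of 11 rose and 0 fell (camera adjusted p = 0.663). These were the chemokine Ccl3 at 1.503 ± 0.11 and, both undetected in wild type, the cyclin Ccnd2 and the costimulatory ligand Cd80, at least 1.71-fold and 1.65-fold higher.

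In the other lists of the innate response, 3 of 43 interferon-stimulated genes rose and 2 fell (camera adjusted p = 0.328), and 2 of 31 NF-kappaB genes rose and 1 fell (camera adjusted p = 0.27). For Toll-like receptor signalling 3 of 27 fell and 1 rose (camera adjusted p = 0.158), with the transcription factor Irf5 at -1.27 ± 0.12. Effector enzymes had 1 of 21 higher and 2 lower (camera adjusted p = 0.873), and MHC class I genes 1 of 17 higher (camera adjusted p = 0.911). In the MHC class II list the costimulatory ligand Cd86 changed by 2.04 ± 0.12 and the class II chain H2-Ab1 by -1.78 ± 0.11, with 2 of 13 higher and 2 lower (camera adjusted p = 0.0638).

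In the unstimulated cells 706 genes were called, 377 higher and 329 lower in the labelled knockout. With median scaling the split was 341 higher and 355 lower, or 382 and 319 relative to a median over all genes of -0.056. Without background correction the count was 327.

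Under LPS, Il1a was the gene with the largest fitted rise in the labelled knockout relative to wild type, at 7.43 ± 0.11. The chemokines Ccl7 and Ccl2 changed by 7.32 ± 0.099 and 7.07 ± 0.16, and Ccl8 was at least 81.1-fold higher. Il6 changed by 5.46 ± 0.18 and Inhba by 5.01 ± 0.12. Csf2, which encodes the growth factor GM-CSF and was undetected in wild type, was at least 11.2-fold higher. Of the inflammatory cytokines 14 of 21 rose and 1 fell (camera adjusted p = 1.58e-09, and adjusted p = 0.0441 with an estimated correlation), and of the chemokines 8 of 17 rose and 1 fell (camera adjusted p = 6.28e-05, and adjusted p = 0.0842 with an estimated correlation). The interferon-inducible gene Ifi202b, the decoy receptor Tnfrsf11b, Ctsl and Hal were at least 50.9-fold, 37.6-fold, 38.0-fold and 31.1-fold higher. The stefin genes Stfa2 and Stfa1, near-identical copies whose probes may not tell them apart, were at least 18.4-fold and 18.9-fold higher. A second probe of Stfa2 read a smaller change of 3.29.

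Fcer1g was again the gene with the largest decrease, at least 869-fold lower. Ifi205 changed by -6.91 ± 0.23, with the probe detected on 1 of 2 labelled knockout arrays, and its other probes read -4.98 and -1.46. Gpr137b-ps changed by -6.37 ± 0.18, Tomm22 by -3.44 ± 0.11, C1qb by -3.16 ± 0.12, Psmd8 by -3.09 ± 0.18, the cyclin-dependent kinase inhibitor Cdkn2b by -3.46 ± 0.12 and Slamf9 by -3.10 ± 0.12. The purine-salvage gene Pnp2, Fblim1 and Tmem51 were at least 9.81-fold, 6.18-fold and 7.76-fold lower. Supt16 changed by -4.58 ± 0.16 on its brightest probe and by 0.31 on the second. The adjusted p of the 24 genes named by rule was at most 3.55e-06. Of those that were lower, only Ifi205 and Supt16 had a further kept probe. The other decreases rest on a single probe each.

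Interferon-stimulated genes under LPS had 7 of 43 lower in the labelled knockout and 1 higher (camera adjusted p = 0.000552, and adjusted p = 0.0633 with an estimated correlation). Mx1 changed by -1.72 ± 0.19 and Ifi35 by -1.66 ± 0.12. Matrix proteases and inhibitors had 10 of 19 higher (camera adjusted p = 6.88e-05, and adjusted p = 0.059 with an estimated correlation), with Serpinb2 at 4.70 ± 0.11 and Plau at 2.43 ± 0.11. Cell-cycle genes had 3 of 39 higher (camera adjusted p = 6.68e-06, and adjusted p = 0.0633 with an estimated correlation). In the list of lipid handling by the nuclear receptors LXR and PPAR, 7 of 19 fell and 2 rose (camera adjusted p = 0.0451, and adjusted p = 0.375 with an estimated correlation), with Apoe at -2.89 ± 0.21 and the desaturase gene Scd1 at 2.01 ± 0.11; this list's call was also lost with median scaling, with no filter on dim probes, and without replicate 2 of wild type LPS or replicate 1 of labelled knockout LPS. Granulocyte markers had 5 of 16 lower and 2 higher (camera adjusted p = 0.000414, and adjusted p = 0.0654 with an estimated correlation). Alternative activation genes had 7 of 14 higher and 2 lower (camera adjusted p = 0.0546), and macrophage identity genes 1 higher and 3 lower (camera adjusted p = 0.0704). Of genes described as repressed by Bcl6 in B cells, 1 of 11 rose, namely Ccnd2 (camera adjusted p = 0.685). The NF-kappaB list had 6 of 31 higher and 1 lower (camera adjusted p = 0.188), with Ier3 at 2.93 ± 0.12. Effector enzymes had 4 of 21 higher and 1 lower (camera adjusted p = 0.113), with Ptgs2 at 3.76 ± 0.15 and Ptges at -2.38 ± 0.17.

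In all, 927 genes were called for the labelled knockout under LPS, 514 higher and 413 lower. With median scaling the split was 318 higher and 769 lower, with a median over all genes of -0.29, and relative to that median it was 531 and 397. Without background correction 412 genes were called. The knockout effects with and without LPS share no array and correlated across genes with r = 0.78. Genes higher in both numbered 250, where independent lists would share 23.3, and genes lower in both numbered 210, where independent lists would share 16.4. No gene was called in opposite directions.

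**Figure D3:**
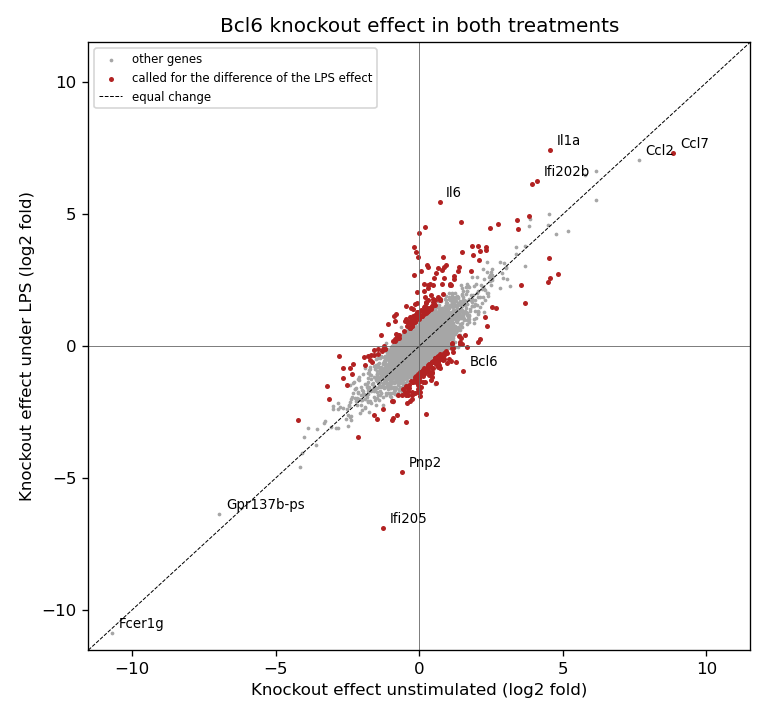
Knockout effect of each of the 8306 genes without LPS (horizontal axis, log2 fold) and under LPS (vertical axis, log2 fold), labelled knockout over wild type, with the dashed line at equal change. Red points are the 318 genes called for the difference of the LPS effect; Ccl7, Ccl2 and Il1a lie far up and right, and Fcer1g lies at the lower left.

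A test of the difference of the LPS effect asked whether the signed LPS change was higher or lower in the labelled knockout than in wild type. A gene that fell further with LPS in the labelled knockout thus counts as lower. Il6 differed by 4.75 ± 0.25, being at least 3.18-fold higher with LPS in wild type, where it was undetected without LPS. Ptgs2 differed by 3.95 ± 0.22, Serpinb2 by 3.24 ± 0.16 and Slamf1 by 4.31 ± 0.16. The growth factors Csf2 and Csf3 differed by 4.29 ± 0.16 and 3.69 ± 0.15, the pentraxin Ptx3 by 3.40 ± 0.24 and the stromelysin Mmp3 by 2.89 ± 0.16. These last 4 were detected only on the labelled knockout LPS arrays, so their sizes depend on the background level of the other groups. In the other direction Ifi205 differed by -5.63 ± 0.32, Pnp2 by -4.16 ± 0.17, Ifi204 by -2.81 ± 0.32 and Rasgrf1 by -2.43 ± 0.18. On a second probe of Ifi205 the knockout effect was -0.39 unstimulated and -4.98 under LPS, and on another 0.012 and -1.46. Both probes thus read a smaller difference than the brightest probe. Pnp2, Ifi204 and Rasgrf1 were detected only on the wild-type LPS arrays. Bcl6 itself differed by -2.47 ± 0.19, Tmem53 by -2.10 ± 0.22, the transcription factor Sox4 by -2.06 ± 0.20 and Plau by -2.05 ± 0.15. Of these 16 genes only Bcl6 and Plau were detected on all 8 arrays, so the sizes of the other 14 depend on the background level in at least 1 group. Ptgs2 and Slamf1 were undetected without LPS in both genotypes, Serpinb2 in unstimulated wild type, and Tmem53 and Sox4 in wild type with and without LPS. The adjusted p of these 16 genes was at most 0.00212.

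Inflammatory cytokines had 10 of 21 members with a larger LPS effect in the labelled knockout and 1 with a smaller one (camera adjusted p = 1.86e-07, and adjusted p = 0.0532 with an estimated correlation). Interferon-stimulated genes had 1 larger and 5 smaller of 43 (camera adjusted p = 0.000195, and adjusted p = 0.059 with an estimated correlation). For the NF-kappaB list 3 of 31 were larger (camera adjusted p = 0.000862, and adjusted p = 0.0654 with an estimated correlation), namely Gadd45b, Pde4b and Socs1. Granulocyte markers had 6 of 16 larger and 1 smaller (camera adjusted p = 2.85e-06, and adjusted p = 0.0532 with an estimated correlation). Matrix proteases had 3 larger and 2 smaller of 19 (camera adjusted p = 0.0153, and adjusted p = 0.104 with an estimated correlation), a call lost without either replicate of labelled knockout LPS. Alternative activation genes had 2 of 14 larger (camera adjusted p = 0.00269, and adjusted p = 0.0823 with an estimated correlation), oxidative phosphorylation 1 of 28 (camera adjusted p = 0.00827, and adjusted p = 0.0842 with an estimated correlation), and cell-cycle genes 0 smaller with a list median of -0.20 (camera adjusted p = 0.00233, and adjusted p = 0.0984 with an estimated correlation). Chemokines had 2 larger and 3 smaller of 17 (camera adjusted p = 0.647). Over all genes 318 were called, 163 with a higher and 155 with a lower LPS effect in the labelled knockout. With median scaling the split was 97 and 316, or 151 and 187 relative to a median over all genes of -0.21, and without background correction the count was 122.

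Averaged over genotypes, LPS called 1102 genes, 580 higher and 522 lower. Relative to a median over all genes of -0.12 these were 687 and 385. With median scaling 545 were higher and 619 lower, or 699 and 412 relative to a median of -0.18. Averaged over treatments, the labelled knockout called 692 genes, 368 higher and 324 lower. With median scaling the split of the mean knockout effect was 285 and 454, or 392 and 319 relative to a median of -0.17. Without background correction the counts were 595 and 327. Among the 580 genes that LPS raised, 67 were called higher and 48 lower in the unstimulated labelled knockout, and 110 higher and 63 lower under LPS. Among the 7726 genes outside that set, 310 were called higher and 281 lower unstimulated, and 404 higher and 350 lower under LPS. The genes that LPS raised were thus called more often in both directions. The median knockout effect of these 580 genes was 0.072 unstimulated and 0.035 under LPS, above 100% and 99.7% of the medians of 10000 random gene lists matched on expression. Among the 522 genes that LPS lowered, 47 were called higher and 44 lower unstimulated, and 38 higher and 52 lower under LPS. The 7784 genes outside this set had 330 higher and 285 lower unstimulated, and 476 higher and 361 lower under LPS. The medians of the 522 genes were -0.040 and -0.11, above 3.12% and 0.10% of random lists. For the 580 genes the unstimulated median turned to -0.00060 without background correction, to -0.00081 with normexp at an offset of 50 and to -0.014 with the authors' processed values. Relative to the median of all genes these were -0.0031, -0.0036 and -0.017. Their median under LPS was -0.20 with median scaling, -0.0061 with the offset of 50 and -0.0085 with the authors' processed values. Relative to the median of all genes it stayed above 0, at 0.087, 0.015 and 0.011, against 0.063 with the settings used.

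Among metabolic and stress genes, glycolysis and hypoxia genes rose with LPS in wild type, 4 of 22 (camera adjusted p = 0.0322, and adjusted p = 0.132 with an estimated correlation), with the oxygen-responsive factor Hif1a at 1.86 ± 0.13. In the labelled knockout the count with LPS was 1 (camera adjusted p = 0.209). The difference of the LPS effect between genotypes was not called for this list (camera adjusted p = 0.21). In the labelled knockout relative to wild type, 3 fell unstimulated (camera adjusted p = 0.0529), among them the pyruvate kinase Pkm at -1.11 ± 0.11, and 2 fell and 1 rose under LPS (camera adjusted p = 0.00325, and adjusted p = 0.0817 with an estimated correlation). Oxidative phosphorylation had 2 of 28 members higher in the labelled knockout under LPS (camera adjusted p = 0.00527, and adjusted p = 0.0824 with an estimated correlation), Sdhd at 1.78 ± 0.11 and Cox7b at least 2.50-fold, and 0 members called lower with LPS in wild type, where the list median was -0.35 (camera adjusted p = 0.0054, and adjusted p = 0.0824 with an estimated correlation). Cholesterol synthesis had 0 of 18 members called in the unstimulated labelled knockout, with a list median of -0.31 (camera adjusted p = 0.0298, and adjusted p = 0.132 with an estimated correlation), a call lost without replicate 2 of that group. For LPS the list gave camera adjusted p = 0.716 in wild type and 0.722 in the labelled knockout. Lipid handling genes gave camera adjusted p = 0.389 for LPS in wild type, where the nuclear receptor Pparg changed by -2.33 ± 0.13. Unfolded protein and heat shock genes had 2 of 19 higher in the unstimulated labelled knockout (camera adjusted p = 0.0316, and adjusted p = 0.185 with an estimated correlation), Pdia4 at 1.46 ± 0.14 and Chac1 at 1.19 ± 0.13.

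Lysosome and phagocytic receptor genes went both ways in the labelled knockout, 4 of 30 higher and 3 lower unstimulated (camera adjusted p = 0.806) and 3 and 3 under LPS (camera adjusted p = 0.492). The inhibitory Fc receptor Fcgr2b changed by 1.73 ± 0.11 unstimulated, and by 2.83 ± 0.11 with LPS in wild type. Osteoclast markers had 0 of 6 called in the labelled knockout unstimulated (camera adjusted p = 0.991) and 0 under LPS (camera adjusted p = 0.632), while with LPS in wild type Jdp2 changed by 2.38 ± 0.11 and Tnfrsf11a by -1.53 ± 0.14. With LPS the list of genes described as repressed by Bcl6 in B cells had 5 of 11 higher and 1 lower in wild type (camera adjusted p = 0.00919, and adjusted p = 0.162 with an estimated correlation), Cd69 and Cxcl10 among the higher. Matrix proteases with LPS in wild type had 6 of 19 higher and 2 lower (camera adjusted p = 0.0451, and adjusted p = 0.151 with an estimated correlation). Several other settings ended this call, such as median scaling. The list median was 0.14 as fitted and 0 with members below background at their bound. The median or mean of a list differed in sign from its test for cholesterol synthesis with LPS in both genotypes, and for glycolysis, unfolded protein and macrophage identity genes with LPS in the labelled knockout. The same held unstimulated for effector enzymes, MHC class I genes, lysosome genes and osteoclast markers in the labelled knockout, for lysosome genes under LPS, and for lipid handling and osteoclast lists in the difference; none of these was called. Dendritic-cell, B-cell, T-cell, erythroid, stromal and mast-cell markers each had too few tested members for a test.

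Counts adjusted over the list alone were equal to those over all genes for all 21 lists in the 4 comparisons between groups. For the difference of the LPS effect they differed in 2 lists, with 4 in place of 3 matrix protease genes higher and 1 in place of 0 cell-cycle genes lower. Of the list calls by camera at its preset correlation, 3 of 13 held with an estimated correlation for LPS in wild type, 3 of 12 in the labelled knockout, 2 of 8 for the knockout unstimulated, 1 of 9 under LPS and 0 of 8 for the difference.

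**Figure D4:**
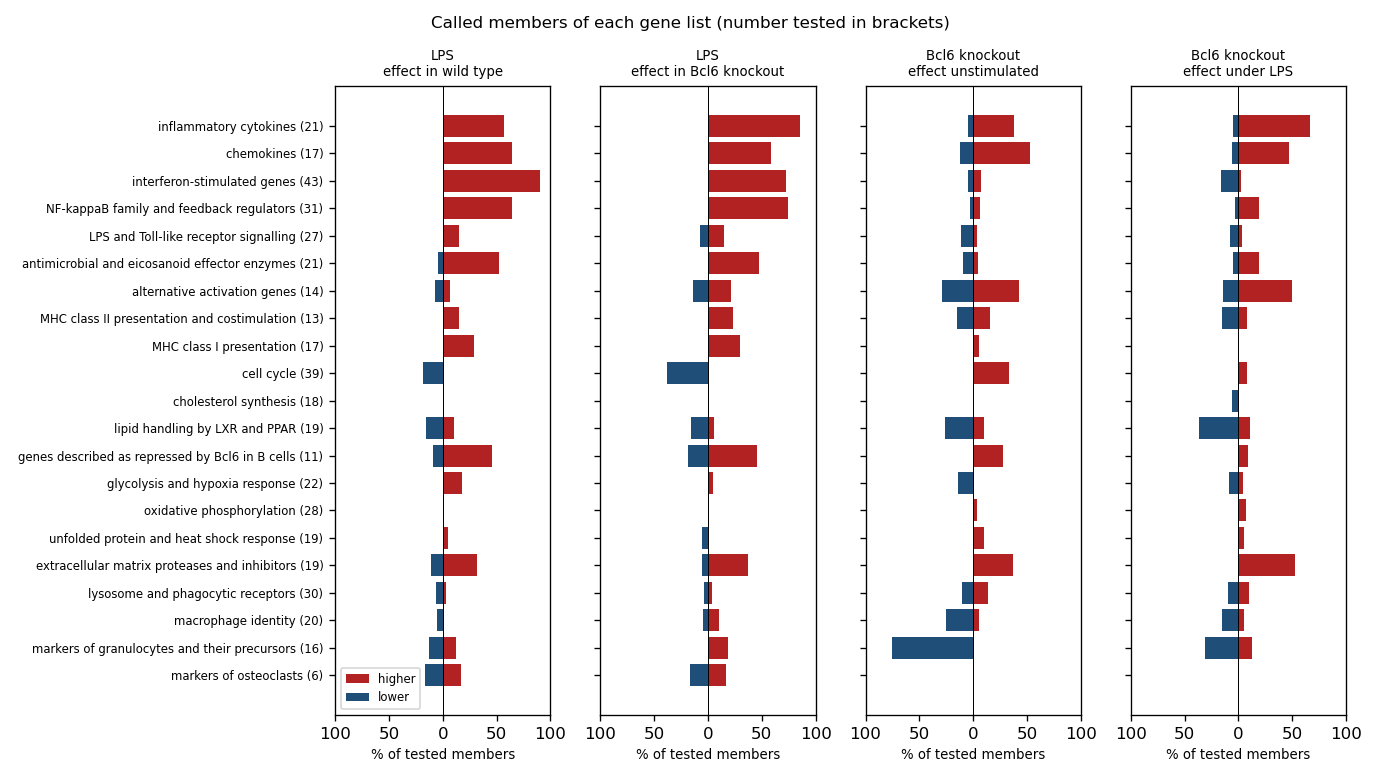
Percent of the tested members of each of the 21 gene lists that were called higher (red, to the right) or lower (blue, to the left), for the LPS effect in wild type, the LPS effect in the labelled Bcl6 knockout, and the knockout effect unstimulated and under LPS. Interferon-stimulated genes reach 39 of 43 higher with LPS in wild type, and granulocyte markers 12 of 16 lower in the unstimulated labelled knockout.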

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

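The numbers that decided both explanations weighed for the difference of the LPS effect were fixed before that result was seen, but the condition on the spread of a value, and the comparison of the authors' values with those without background correction, were set after the values were seen. The LPS effect differed between the genotypes, by limma's test of the difference itself, for 318 of 8306 genes. Among the genes named by rule, the signed LPS effect was higher in the labelled knockout by 4.75 for Il6, 4.31 for Slamf1, 4.29 for Csf2, 3.95 for Ptgs2, 3.69 for Csf3, 3.40 for Ptx3, 3.24 for Serpinb2 and 2.89 for Mmp3, in log2 units. It was lower, with differences of -5.63 for Ifi205, -4.16 for Pnp2, -2.81 for Ifi204, -2.47 for Bcl6, -2.43 for Rasgrf1, -2.10 for Tmem53, -2.06 for Sox4 and -2.05 for Plau. A lower effect is not always a weaker one. With LPS, the mean log2 signal of Bcl6 went from 12.47 to 9.93 in the labelled knockout and from 10.94 to 10.87 in wild type. That of Plau went from 12.23 to 11.27 in the labelled knockout and from 7.75 to 8.84 in wild type. Tmem53 and Sox4 also fell with LPS in the labelled knockout. The other probes of Ifi205 read smaller differences. Of these 16 genes only Bcl6 and Plau were detected on all 8 arrays, so the sizes of the other 14 depend on the background level in at least 1 group. By camera at its preset correlation, the median difference was 0.87 for inflammatory cytokines, 0.35 for the NF-kappaB list, 0.49 for alternative activation genes, 0.18 for oxidative phosphorylation, 0.42 for matrix proteases and 0.71 for granulocyte markers, and it was -0.23 for interferon-stimulated genes and -0.20 for cell-cycle genes. None of these 8 list calls held with an estimated correlation.

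The 318 genes were the pattern weighed. Lower overall signal on the labelled knockout LPS arrays may account for some of them. Changing the scaling alone gave 413 genes with median scaling and 319 with cyclic loess, so no fall followed from scaling. The authors' processed values gave 120, a fall past the bound fixed beforehand, but the main scaling without background correction gave 122, so the authors' values do not separate scaling from background correction and the question stays open. Of the called genes 46.9% (149 of 318) were detected on all 8 arrays, with an exact 95% interval of 41.3% to 52.5%, against 78.1% of all tested genes; a gene silent before LPS meets this too, so changes near background cannot be told apart from induction. The genotype itself stays open as a biological explanation, untested here, since the labels name no independent cultures.

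Probes without a single gene name in the annotation used stood outside every comparison. Of 1876 such probes that passed the detection filter, 176 were called for the mean LPS effect and 147 for the mean knockout effect.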

How the results depend on the processing

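The alternatives that drop genes with disagreeing probes, that set list medians to their bounds and that use median scaling for lists were chosen after seeing the data; the others were fixed before. The 7 counts are, in order, LPS in wild type and in the labelled knockout, the knockout effect unstimulated and under LPS, the difference of the LPS effect, and the mean LPS and mean knockout effects; the main values were 1165, 1233, 706, 927, 318, 1102 and 692. Over all alternatives there were 305 values of these counts, of the medians and r of the knockout effect and of the Bcl6 change. Of them 221 stayed within 1.5 times of a count, within the spread or on the same side of the threshold, 77 moved further, 4 passed a threshold they had missed, and 3 turned direction. Among the 77, the median under LPS among genes higher with LPS also fell below 0 in 3, with median scaling, the offset of 50 and the authors' processed values, but stayed above the median of all genes, by 0.087, 0.015 and 0.011. Of 1764 values for lists 1636 kept their call and direction, 60 lost the call, 68 gained one and 0 turned. The 84 values with members at their bound carry the p of the main fit. Their call was thus fixed in advance, and only their direction could turn. Of 10126 values for named genes 9617 kept both, 250 lost the call, 259 gained one and 0 turned. The cause of these shifts was not tested, except that a smaller fold minimum passes more genes by construction, and that counting probes counts a gene several times. Signal over background limits the folds of dim probes.

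Without background correction, the 7 counts were 635, 641, 327, 412, 122, 595 and 327. Median knockout effects were -0.00060 unstimulated among genes higher with LPS, 0.0036 under LPS among genes higher with LPS, -0.0077 unstimulated among genes lower with LPS and -0.039 under LPS among genes lower with LPS. The r of the knockout effects was 0.786. With normexp at an offset of 50, the 7 counts were 729, 764, 380, 499, 151, 690 and 395. Median knockout effects were -0.00081 unstimulated among genes higher with LPS, -0.0061 under LPS among genes higher with LPS, -0.018 unstimulated among genes lower with LPS and -0.071 under LPS among genes lower with LPS. The r of the knockout effects was 0.789. With the authors' processed values, the 7 counts were 637, 651, 340, 419, 120, 600 and 327. Median knockout effects were -0.014 unstimulated among genes higher with LPS, -0.0085 under LPS among genes higher with LPS and -0.081 under LPS among genes lower with LPS. The r of the knockout effects was 0.786. With median scaling, median knockout effects were 0.034 unstimulated among genes higher with LPS, -0.20 under LPS among genes higher with LPS, -0.087 unstimulated among genes lower with LPS and -0.33 under LPS among genes lower with LPS. Bcl6 under LPS was -1.26, past the threshold, but -0.97 relative to a median over all genes of -0.29, short of 2-fold. With cyclic loess, median knockout effects were 0.072 under LPS among genes higher with LPS and -0.0012 under LPS among genes lower with LPS. Without a filter on dim probes, the r of the knockout effects was 0.724. With probes detected on at least 4 arrays, the r of the knockout effects was 0.806. Without a fold minimum, the 7 counts were 4094, 4132, 3010, 3647, 674, 5144 and 4426. The median knockout effect was -0.072 under LPS among genes lower with LPS. Bcl6 under LPS was -0.94, past the threshold. At a fold of at least 1.5, the 7 counts were 2626, 2681, 1785, 2245, 671, 2510 and 1857. The median knockout effect was -0.058 unstimulated among genes lower with LPS. Bcl6 under LPS was -0.94, past the threshold. With every probe on its own, the 7 counts were 1948, 2015, 1142, 1666, 608, 1762 and 1156. The median knockout effect was -0.060 unstimulated among genes lower with LPS. The r of the knockout effects was 0.756.

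Leaving out each array in turn left 1 array in its group, assumed to vary like the others. The counts then ranged from 1164 to 1185, 1223 to 1298, 691 to 726, 914 to 979, 256 to 305, 1089 to 1121 and 688 to 724. Median knockout effects ranged from 0.042 to 0.088 unstimulated among genes higher with LPS, 0.0076 to 0.068 under LPS among genes higher with LPS, -0.055 to -0.026 unstimulated among genes lower with LPS and -0.17 to -0.076 under LPS among genes lower with LPS. The r of the knockout effects ranged from 0.765 to 0.781. The Bcl6 change ranged from 1.40 to 1.67 unstimulated and from -1.06 to -0.82 under LPS, where it passed the threshold only without replicate 1 of wild type LPS. With the replicate number as a block, the counts were 1165, 1233, 706, 927, 316, 1102 and 692. The deviations of arrays with the same replicate number correlated at -0.031 to 0.0084 between groups, so the numbers do not pair the arrays. The slide as a block was not run, since no slide is given. Averaging arrays to 1 value per group, in an additive fit with 1 residual degree of freedom, called 1082 genes for LPS and 665 for the knockout. Without genes whose probes disagree, 651, 835 and 638 genes were called for the knockout effect unstimulated, under LPS and on average.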

Other observations

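Tests of sequence variants and of chromosome segments were chosen only after the results were seen, as were the conditions on the spread of the tests of segments and of genes near Bcl6. Markers of 6 further cell types had 1 or 2 tested members each. The mast-cell growth factor receptor Kit, detected in wild type and not in the unstimulated labelled knockout, was at least 1.62-fold lower there. Hdc, which makes histamine, was at least 1.75-fold lower in the unstimulated labelled knockout and at least 10.4-fold higher with LPS in it. With LPS in wild type its change was 1.73 ± 0.13 in log2 units, a different scale from that fold. Among dendritic-cell markers, Batf3 was at least 4.17-fold higher in the labelled knockout under LPS, and Fscn1 was at least 2.22-fold higher with LPS in wild type. The T-cell markers Cd28 and Cd8b1 changed with LPS in wild type by -2.20 ± 0.14 and -1.23 ± 0.13. In the labelled knockout they changed with LPS by -2.59 ± 0.14 and -1.15 ± 0.13. Neither marker was called for the knockout effect, with or without LPS. The erythroid marker Car2 was at least 1.32-fold higher in the labelled knockout under LPS. The B-cell markers Blnk and Cd22 changed by 0.23 ± 0.12 and 0.61 ± 0.20 in the unstimulated labelled knockout, and the stromal markers Acta2 and Vim by 0.56 ± 0.12 and 0.38 ± 0.12, all short of 2-fold.

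Genes called for the mean knockout effect, 692 in number, were the main pattern weighed. The knockout effects unstimulated and under LPS, which share no array, correlated across genes at r = 0.779, which argues against an error of 1 dish or hybridisation as the whole cause. The labels do not say whether cells with and without LPS came from the same mouse or culture. A difference between single mice or cultures of the genotypes could give the same r, so it stays open. Fewer cells of the granulocyte lineage in the labelled knockout cultures may account for a part: their 16 tested markers, 3 of which other lists also hold, had a median of -1.65 unstimulated and -0.823 under LPS, with mean log2 signals in unstimulated wild type of 13.73 for S100a8 and 12.48 for S100a9, and 12.51 and 10.76 in the unstimulated labelled knockout. Of these markers 12 were lower and 0 higher unstimulated, but 5 were lower and 2 higher under LPS. Their signed LPS effect was higher in the labelled knockout for 6 and lower for 1, so the deficit was not the same in both treatments. No sort or gate is given in the labels, and macrophages express some of these genes. Sequence variants under single probes may account for another part. Among called genes with more than 1 kept probe, 54 of 201 (26.9%) had a disagreeing probe. For the mean LPS effect it was 50 of 389 (12.9%), a ratio of 2.09 (Fisher's exact p = 3.66e-05). Among called genes with any number of probes, 218 were called for both effects. The test treats the sets as separate, so its p is only a guide. Why probes disagree was not tested. Passenger DNA around the targeted gene stays open: 11 of the 100 tested genes nearest to Bcl6 were called, 1.33 times the 8.30% among other genes, with an interval of 0.677 to 2.27 (Fisher's exact p = 0.359). Segments of another strain also stay open, although the labels give both genotypes the same background. Of the called genes, 332 had another called gene among the 3 nearest tested genes on either side. The mean in 1000 shuffled gene orders was 280.7, a ratio of 1.18 (permutation test, p = 0.002). Called genes thus lay closer together than in shuffled orders, but the ratio lies within its spread of the bound of 1.2. The mean LPS effect had a ratio of 1.07 (permutation test, p = 0.014). On chromosome 1, 13.4% of tested genes were called for the mean knockout effect. Whether these lie in 1 segment was not tested.

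Of the 35 splits of the 8 arrays into 4 and 4, 1 gave as many genes as the split by LPS, which was that split itself with 978, and the highest other, the split by genotype, gave 479. For the mean knockout effect 2 of 35 did, the real split with 479 and the split by LPS with 978, and the highest of the remaining splits gave 0. The arrays of a group are technical replicates, and only 3 of these splits keep each group whole, too few for a share under 0.05. These fits had 1 mean for each side of the split, so their counts differ from those of the 4-group fit. Genes called for the mean knockout effect made up 13.4% of tested genes on chromosome 1 (adjusted p = 0.00388) and 4.04% on chromosome 8 (adjusted p = 0.00388), by Fisher's exact test over chromosomes. For the mean LPS effect the share on chromosome X was 6.20% (adjusted p = 0.00981).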
